A study of Mus musculus with 9 samples.

How the data were processed

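RNA from cells harvested after 3 days of LSK culture on OP9 feeder layers was measured on 9 single-colour oligonucleotide arrays, 3 from each of 3 groups: OP9-GFP, OP9-DL1, and OP9-DL1 with 1 µM Compound E. Per the labels' protocols, 25 ng of RNA was amplified and biotin-labelled, a step that favours the 3′ ends of transcripts. The 3′ probe sets of Actb read 0.51 to 0.65 above the 5′ ones (log2) and those of Gapdh 0.54 to 0.69, over the 9 arrays. Groups and replicate numbers came from the sample titles.

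The authors deposited 1 log2 value per probe set and array. Per the submitters' processing notes, MAS5 and GCRMA 2.4.1 were used, with no role or order given. The range of the deposited log2 values and their nearly equal quartiles resemble GCRMA output, but which step produced them is not given in the sources used here. Array medians ran from 4.78 to 4.94. No pair of arrays was identical, but 20489 of the 45101 probe sets held the same value on 2 or more arrays, bright ones included, for a reason not given in the sources used here. Within a group this held for 11.2% of genes on OP9-GFP, 7.44% on OP9-DL1 and 5.48% with Compound E, and it lowers the replicate spread behind their p-values. GCRMA shrinks dim values towards a floor, so if it produced the values, a fold against a dim group is understated. The table holds no detection calls, so background was judged, after the data were seen, by 27 probe sets for bacterial transcripts, whose values ran from 2.24 to 3.64 with a median of 2.78. Depth has no counterpart on an array, and the 3 arrays per group limit the precision.

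Probe sets were named through the platform annotation supplied with the values. Of 45101 probe sets 34945 had 1 gene symbol, 932 several, 9160 none and 64 were array controls. For 34741 of those with 1 symbol the symbol was updated through the Entrez ID, with a RefSeq table of the assembly GRCm38.p6 used for names only. Each of 18193 genes was represented by its probe set with the highest mean over all 9 arrays, and 9183 genes had only 1. Among the 50 entries ranked by size, 26 had other probe sets, and in 5 of these none moved the same way by more than 0.5. No coordinates are given, because no genome build was used.

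Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with an intensity trend) on the deposited log2 values of all 9 arrays, with no covariate, no further normalization and no filter on dim genes. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Errors given as SD are between the 3 arrays of a group, and those given as SE are from the model. In addition 16 gene lists, with 13 to 27 measured members, were tested with camera at an inter-gene correlation of 0.01, adjusted over 48 tests, of which 34 were called. With an estimated correlation 29 were called, all but 5 of the 34, and those 5 are named beside their values. Fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, called 40. For overlaps and correlations between comparisons that share arrays, unchanged groups were simulated 100 times.

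The groups, tests, lists, alternatives other than the filters on background and on equal values, and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls in each of the first 2 comparisons and 5 of each in the third, among genes with an adjusted p under 0.05 and no overlap between groups, skipping clone-like symbols. It added every measured Notch target and, from each other list, up to 4 members with the smallest p in each of the first 2 comparisons. Genes outside the rule are said to have been chosen after their values were seen. The procedure was tested on simulated data made from OP9-DL1 against OP9-GFP with 18193 genes. It recovered 64.2% of 67 genes changed 1.5-fold, 98.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 6 false calls among 181. Camera gave an unadjusted p under 0.05 for 3 of 100 random lists there. The simulated genes varied independently, so this cannot show how often camera calls lists of correlated genes in error.

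Alternatives were log2(value + 32) on the linear scale, quantile normalization, centring each array on its median, only the genes above the median brightness, the mean of a gene's probe sets, no intensity trend, only the 6 arrays compared, the replicate number as a block, each array left out in turn, a 2-fold threshold, all probe sets in place of genes, and the other set tests. Filters on genes above background and on genes with no equal values within any group were added after the data were seen. The alternative of log2(value + 1) was meant for linear values and did not apply.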

Results

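Gene expression was measured on 9 oligonucleotide arrays in cells harvested from cultures of mouse bone marrow LSK cells. LSK cells are the lineage-negative, Sca-1-positive and c-Kit-positive fraction that is enriched for hematopoietic stem and early progenitor cells. Sorted C57/Bl6 LSK cells were kept for 3 days on a feeder layer of OP9 cells, a mouse bone marrow stromal line, and the cells that had not attached to the dish were harvested. There were 3 arrays from cultures on OP9-GFP, the control feeder. A further 3 came from cultures on OP9-DL1, a feeder made to express the Notch ligand Delta-like 1, and 3 from OP9-DL1 with 1 µM Compound E, a γ-secretase inhibitor. γ-Secretase cuts a ligand-bound Notch receptor and so frees the part that acts in the nucleus. The comparisons address what Notch signalling changes in these cultures and how much of that change an inhibitor of receptor cleavage removes. Genes listed as stromal markers were bright, with log2 means over the 9 arrays of 12.28 for Cxcl12 and 11.67 for Sparc. The RNA may therefore hold a share from feeder cells. A change in a gene that feeder cells also express cannot be assigned to the LSK-derived cells. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

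Each array gave a log2 value for 45101 probe sets, and 18193 genes were tested, each by 1 probe set. The number of arrays limits the precision: the median standard error of a log2 difference was 0.10, and the median SD between replicates was 0.09 on OP9-GFP, 0.09 on OP9-DL1 and 0.12 with Compound E. Exactly equal values stood on 2 or 3 arrays of a group for 3976 genes (21.9%), and on all 3 arrays for 350, among them Pf4, Msr1 and Nop58 on OP9-GFP, so the spread of such genes may be understated. Across probe sets, which are not independent replicates, arrays of one group correlated with r of 0.9966 to 0.9984. Between groups r was 0.9919 to 0.9943 for OP9-GFP and Compound E, 0.982 to 0.9833 for OP9-GFP and OP9-DL1, and 0.9726 to 0.9759 for OP9-DL1 and Compound E. The first principal component took 74.8% of the variance and set the OP9-DL1 arrays apart from the other 6. Array probe sets for bacterial transcripts, which mouse RNA should not bind, reached 3.64, and values up to that level are called background here. That maximum came from Compound E replicate 2, and the maxima of the other arrays were 3.13 to 3.45. A value just below 3.64 can therefore lie above all such controls of its own array. Folds of genes that are at background in 1 group may be understated by an unknown amount, so their ranks by size are uncertain too.

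Delta-like 1 itself could not check the labels. Its probe set read 3.25 on OP9-GFP, 3.29 on OP9-DL1 and 3.29 with Compound E, all at background, and the probes may lie outside the introduced sequence. Nrarp, a Notch target that feeds back on the receptor complex, did set every OP9-DL1 array apart. Its mean was 6.61 ± 0.02 on OP9-GFP, 9.30 ± 0.12 on OP9-DL1 and 5.02 ± 0.23 with Compound E (log2, SD, n = 3 in each group).

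**Figure D1:**
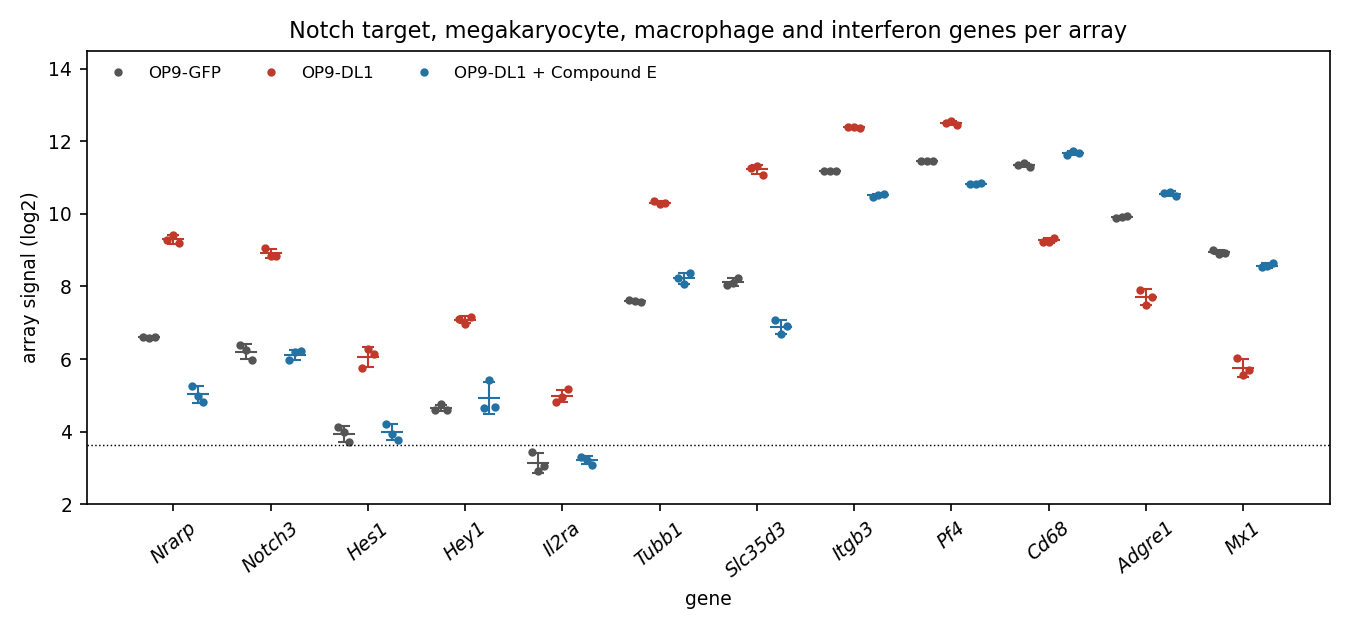
Array signal (log2) of 12 genes in the 3 groups. Points are single arrays, bars are the mean ± SD of 3 arrays, and the dotted line is the brightest bacterial control value, 3.64. Notch targets and megakaryocyte genes peaked on OP9-DL1, with Nrarp at 9.30 against 6.61 on OP9-GFP, while Cd68, Adgre1 and Mx1 were lowest there.

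OP9-DL1 was first compared with OP9-GFP, which asks what the ligand-expressing feeder changed. Notch targets, megakaryocyte genes, mast cell genes and several early T cell genes rose on OP9-DL1, while macrophage and interferon-response genes fell. Among megakaryocyte and platelet genes 26 of 27 rose, with a median log2 change of 1.5, and among monocyte, macrophage and dendritic cell genes 19 of 21 fell, with a median of -1.10. In all, 2888 genes were higher and 3046 lower at a limma adjusted p below 0.05, and 748 of the higher and 502 of the lower ones changed at least 2-fold. The share of higher among changed genes was 48.7%, and 41.6% when each array was centred on its median and 48.6% over all probe sets. The 3 values of each group did not overlap for 43.8% of genes, where chance gives 10%.

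The largest rise was that of Adamdec1, a disintegrin-like metalloprotease, from 3.06 ± 0.03 to 9.97 ± 0.03 (SD, n = 3), 120-fold, with a limma adjusted p of 3.9e-15. Its level on OP9-GFP was at background. Gzmb, the cytotoxic protease granzyme B, rose by a log2 of 5.40 ± 0.20 (SE) from 5.86 to 11.26. The mast cell protease gene Mcpt1 (log2 5.13), the transcription factor gene Spic (4.55), the chemokine receptor gene Ccr7 (4.40), the T cell receptor variable segment Trbv1 (5.88) and the anion exchanger gene Slc26a7 (5.61) all rose from background. Stfa2l1, a stefin gene (4.76), Col8a1, a collagen chain gene (4.53), and Chodl (4.35) completed the 10 largest rises. The largest fall was that of Gpnmb, a glycoprotein of macrophages and pigment cells, by 4.56 ± 0.07 (SE) from 11.14 ± 0.03 to 6.58 ± 0.12 (SD, n = 3), with an adjusted p of 1.97e-16. Pid1 (-4.52), the neutrophil collagenase gene Mmp8 (-4.52), the endothelin receptor gene Ednrb (-4.49), the kallikrein gene Klk1b11 (-4.16), Tctex1d1 (-4.05), Olfm1 (-3.81), Ms4a7 (-3.79), Adgb (-3.73) and Tmem171 (-3.67) were next, of which Klk1b11 and Adgb fell to background. Other probe sets of 6 of these genes moved far less, by at most 0.06 for Trbv1, 1.15 for Slc26a7, 0.87 for Col8a1, -0.85 for Pid1, -1.10 for Ednrb and -0.48 for Ms4a7. With probe sets averaged these genes stood at 2.97, 3.38, 2.09, -1.85, -2.02 and -2.14, each still called. A call after averaging, here and below, can rest on 1 far-moving probe set. It does not settle which probe set is right.

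Of 13 Notch targets 8 rose and 1 fell (10 and 1 when adjusted over the list alone), with a median log2 change of 1.56 and a camera adjusted p of 2.16e-06. Notch3, a Notch receptor gene that is itself a target, rose by 2.71, Nrarp by 2.69, Hey1 by 2.43 and Hes1 by 2.12, the last 2 being transcriptional repressors. Il2ra, the interleukin 2 receptor α chain (1.86), the transcription factor gene Gata3 (1.64) and Dtx1 (1.56) rose from background, and Myc rose by 1.05. With probe sets averaged Il2ra stood at 0.98. With log2(value + 32) Il2ra stood at 0.64, Gata3 at 0.61, Dtx1 at 0.52, Hes1 at 1.06 and Hey1 at 1.55, each still called. Notch1 fell by 0.28, a call that ended when all its probe sets were averaged (adjusted p = 0.0563, the highest over its alternatives, the lowest being 0.00024). Hes5 (0.04), Heyl (0.00), Hey2 (0.30) and Ptcra (0.31) did not pass the test, and the last 3 were at background in every group. Over the alternatives the adjusted p of Hey2 ran from 0.0288 to 0.256 and that of Ptcra from 0.00977 to 0.239, and single arrays changed both calls: Hey2 passed without OP9-DL1 replicate 1 (0.0336) and without Compound E replicate 1 (0.0288), and Ptcra without OP9-DL1 replicate 3.

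Of 27 megakaryocyte and platelet genes 26 rose (26 adjusted over the list alone, camera adjusted p = 3.45e-26). Slc35d3, a transporter gene of platelet dense granules, rose by 3.10, and Tubb1, the platelet β-tubulin, by 2.70. Clec1b, a platelet receptor, rose by 1.75, Rab27b, needed for platelet granule release, by 1.5, the integrin β3 gene Itgb3 by 1.20 and platelet factor 4, Pf4, by 1.06. Markers of the feeder rose with them: 17 of 24 stromal genes were higher (17 higher and 1 lower over the list alone), with a median of 0.59 and a camera adjusted p of 1.53e-10. The stromal rise was 2.08 for Ccn2, 1.89 for Col3a1, 1.67 for Tagln, 1.33 for Fstl1, 1.19 for Timp3 and 1.14 for Ccn1. Erythroid genes rose in 10 of 20 cases (10 over the list alone, median 0.39, camera adjusted p = 3.95e-05). Gata1, which drives erythroid and megakaryocyte genes alike, rose by 2.15, Hemgn by 2.11, Samd14 by 1.98, the carbonic anhydrase gene Car2 by 1.68 and the water channel gene Aqp1 by 1.20. The α-globin gene Hba-a1 (2.79 on OP9-GFP, 2.73 on OP9-DL1) and the heme synthesis gene Alas2 (2.90 and 2.78), both named after their values were seen, were at background.

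Mast cell and basophil genes rose in 9 of 14 cases and fell in 2, with the same counts over the list alone (median 0.78, camera adjusted p = 5.55e-05). The proteases Gzmb and Mcpt4 (2.96, from background), the transcription factor Gata2 (1.82) and the carboxypeptidase Cpa3 (1.34) were among the rises, and Mitf, a regulator of mast cells and other lineages, fell by 1.56. Of 22 hematopoietic stem cell genes 14 rose and 3 fell (14 and 4 over the list alone), with a median of 0.52 and a camera adjusted p of 7.11e-06. These rises included the angiopoietin receptor gene Tek (2.15), Gata2, which also stands in the mast cell list, Sox4 (1.44, or 0.88 with probe sets averaged), Angpt1 (1.22) and Egr1 (1.05). Early T cell genes rose in 10 of 16 cases and fell in 2 (11 and 2 over the list alone, median 0.84, camera adjusted p = 0.000605), of which 1 rise and 1 fall were at background in both groups. Cd7 rose by 2.46 and Cd28, a costimulatory receptor gene, fell by 2.11, and Gata3 and Il2ra stand in the Notch list too. In the brighter part of the genes only Cd28 was left of this list, the direction reversed and the call was lost (adjusted p = 0.0804, the lowest over camera's alternatives being 0.000216). Immediate early and stress genes rose in 15 of 21 cases and fell in 3 (16 and 3 over the list alone, median 0.48, camera adjusted p = 1.69e-06), including 1 rise at background in both groups, with Hspa1b at 1.65, Egr2 at 1.26, Dusp1 at 0.76 and Atf3 at -1.14.

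Of 21 monocyte, macrophage and dendritic cell genes 19 fell and 1 rose (19 and 1 over the list alone, camera adjusted p = 8.55e-17). The exceptions were MHC class II genes: H2-Aa rose by 0.21, and H2-Ab1 (0.07) was not called. The mannose receptor gene Mrc1 fell by 3.59, Adgre1, a macrophage marker, by 2.21, Cd68 by 2.08, the endotoxin coreceptor gene Cd14 by 1.68, Mpeg1 by 1.59 and Cybb, a subunit of the phagocyte oxidase, by 1.13. Interferon-response genes fell in 14 of 17 cases (15 over the list alone, median -0.93, camera adjusted p = 1.25e-10). Mx1, an antiviral GTPase gene, fell by 3.18, Ifit3 and Oas1a by 1.45 each, Ifit1 by 1.07, Rsad2 by 1.02 and Rtp4 by 0.67. Granulocyte genes moved both ways, 7 higher and 9 lower of 19, with the same counts over the list alone, and the list was not called (camera adjusted p = 0.866). The granule genes Ltf (2.83), Camp (2.45), Lcn2 (1.74) and Ngp (1.5) rose, whereas Mmp8 and the growth factor receptor gene Csf3r (-0.74) fell. The granulocyte median was -0.10, its mean 0.12 and the test's direction upward.

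Of 25 cell cycle genes 13 fell and 3 rose (13 and 4 over the list alone, median -0.14, camera adjusted p = 0.015). This call did not hold with an estimated correlation between genes (adjusted p = 0.234 with an estimated correlation) or in the brighter part of the genes (0.0804). Ccne1 fell by 0.64, Aurka by 0.60 (-0.40 with probe sets averaged), Plk1 by 0.56 and Mki67 by 0.44, and the replication gene Mcm4 rose by 0.23. Ribosome biogenesis and MYC genes rose in 7 of 21 cases and fell in 1, with the same counts over the list alone (median 0.12, camera adjusted p = 0.00788), and adjusted p was 0.17 with an estimated correlation. Odc1 (0.38), Dkc1 (0.36), Nop58 (0.29) and Gnl3 (0.19) rose. Another 3 lists were not called. B cell genes had 4 higher and 3 lower of 18, with the same counts over the list alone (camera adjusted p = 0.237), among them Dntt (2.02), Ebf1 (0.82), Cd79b (-0.81) and Lax1, which rose from background (3.02). Blnk (-1.01) is 1 of the 3 lower ones, but it was at background in every group, so its value is no measure of a change. The p53 response list had 8 higher and 2 lower of 19, or 8 and 4 over the list alone (camera adjusted p = 0.114), with Eda2r at 1.72, Perp at 0.90 and Fas at -1.45. Cholesterol synthesis genes had 2 higher and 3 lower of 17, with the same counts over the list alone (camera adjusted p = 0.972, median 0.00, mean -0.03), with Lss at 0.40 and Mvd at -0.60. Some list medians moved by over 1.5 times with the processing. With log2(value + 32), which shrinks changes of dim genes, they were 0.61 for Notch targets, 0.26 for early T cell, 0.42 for mast cell and 0.22 for erythroid genes. With probe sets averaged the early T cell median was 0.49, and with arrays centred on their medians that of ribosome biogenesis was 0.07. In the brighter part of the genes the erythroid median was 1.83 and the stem cell median 1.05, and among genes without equal values the erythroid median was 0.58. All of these stayed called in the same direction. Other splits of the 9 arrays into 3 groups called a median of 24 and up to 33 of the 48 list tests, against 34 for the real groups, so a camera call alone does not set a list apart and the member counts stand beside each one.

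**Figure D2:**
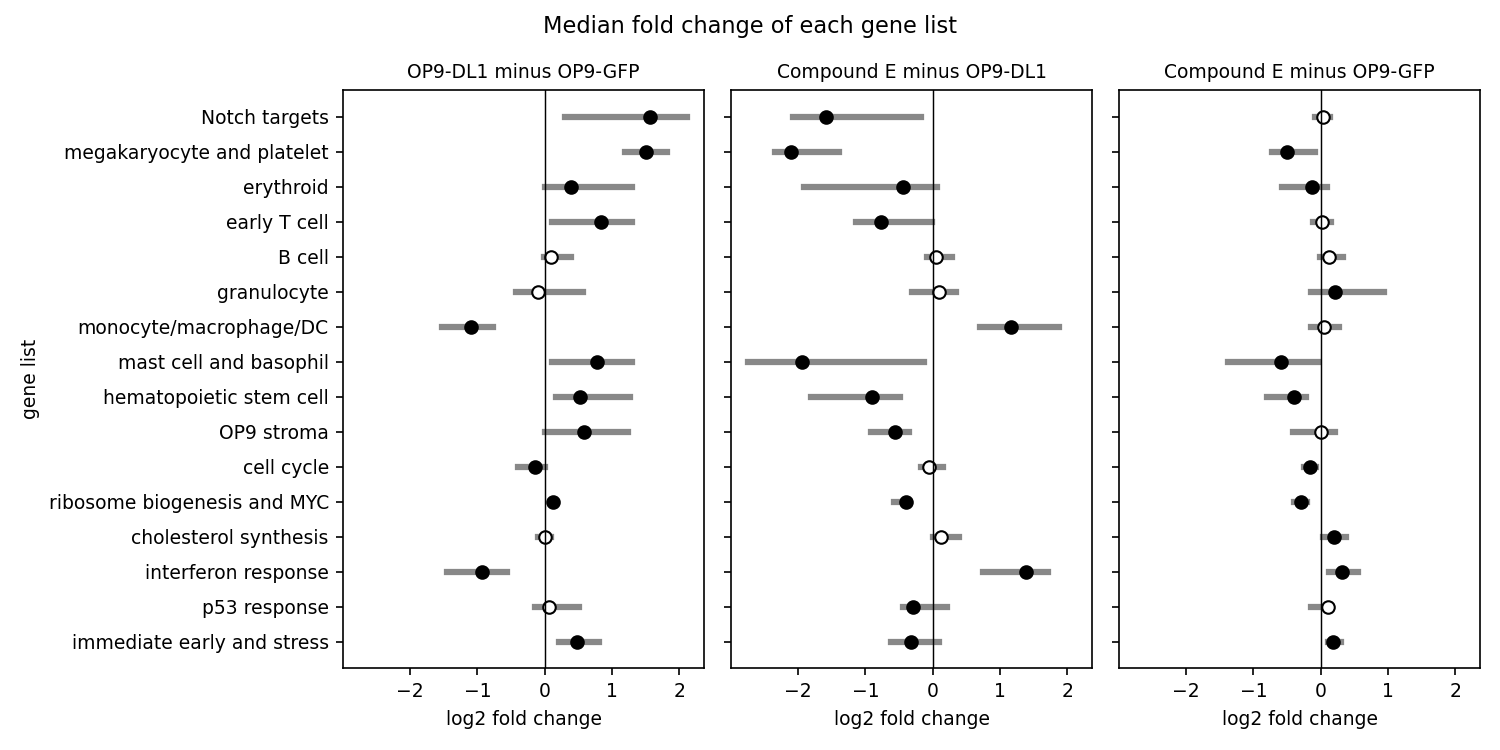
Median log2 fold change of each of the 16 gene lists in the 3 comparisons. Points are medians over the measured members, filled where camera called the list, and grey bars span the 25th to the 75th percentile. The megakaryocyte list stood at 1.5, -2.11 and -0.50 in the 3 panels, and the interferon list at -0.93, 1.39 and 0.31.

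The second comparison, Compound E on OP9-DL1 against OP9-DL1 alone, asks what the inhibitor changed on the ligand-expressing feeder. Notch targets and megakaryocyte, mast cell and stem cell genes fell with Compound E, and macrophage and interferon-response genes rose. The megakaryocyte list fell in 26 of 27 genes, with a median log2 change of -2.11, and the macrophage list rose in 19 of 21, with a median of 1.17. Higher values were found for 4574 genes and lower ones for 3926 (limma adjusted p below 0.05), of which 814 and 900 changed at least 2-fold. The share of higher among changed genes was 53.8%, and 73.7% when each array was centred on its median and 48.9% over all probe sets. Groups did not overlap for 52.6% of genes, where chance gives 10%.

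The largest rise with Compound E was that of Mmp8, from 5.78 ± 0.31 to 11.16 ± 0.07 (SD, n = 3), with a limma adjusted p of 2.93e-15. The acute phase gene Saa3 rose by 4.68, the NAD-consuming surface enzyme gene Bst1 by 4.66, Gpnmb by 4.60 and Pid1 by 4.35. The apolipoprotein gene Apoc2 (4.14), the fatty acid binding protein gene Fabp7 (4.07), Olfm1 (4.06), the macrophage scavenger receptor gene Msr1 (4.03) and the arginase gene Arg2 (3.98) followed. The largest falls were those of Adamdec1, by 6.90 ± 0.13 (SE) to 3.07 ± 0.21 (SD, n = 3), and of Gzmb, by 6.66 ± 0.20 (SE). Trbv1 (-5.68), Mcpt1 (-5.08), the T cell receptor segment Trbv13-2 (-4.50), Spic (-4.37), Slc35d3 (-4.34), Nrarp (-4.27), the DNase gene Dnase1l3 (-4.25) and Ccr7 (-4.25) were next. Adamdec1, Trbv1, Mcpt1, Dnase1l3 and Ccr7 fell to background. Other probe sets moved by at most 1.06 for Pid1, -0.69 for Dnase1l3 and 0.05 for Trbv1, and with probe sets averaged these genes stood at 1.91, -2.47 and -2.81, each still called.

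Notch targets fell in 9 of 13 cases and rose in 1, with the same counts over the list alone (median -1.59, camera adjusted p = 3.11e-05). After Nrarp the falls were those of Notch3 (-2.79), Hey1 (-2.17), Hes1 (-2.08), Myc (-1.86), Il2ra (-1.78), Dtx1 (-1.59) and Gata3 (-1.54), the last 3 to background, and Notch1 rose by 0.31. With probe sets averaged Il2ra stood at -0.88 and Notch1 at 0.19. With log2(value + 32) Il2ra stood at -0.63, Gata3 at -0.59, Dtx1 at -0.52, Hes1 at -1.05 and Hey1 at -1.42, each still called. Hey2 (-0.51) was called too, but both of its group means were at background. Megakaryocyte genes fell in 26 of 27 cases and rose in 1, also over the list alone (camera adjusted p = 1.52e-23). Values were -2.29 for Rab27b, -2.24 for Clec1b, -2.08 for Tubb1, -1.87 for Itgb3 and -1.68 for Pf4. Stromal markers fell beside them, 20 of 24 lower and 1 higher (20 and 2 over the list alone), with a median of -0.57 and a camera adjusted p of 9.82e-11. Among them were Ccn2 (-2.48), Timp3 (-1.94) and Ccn1 (-1.74, or -1.09 with probe sets averaged). Erythroid genes fell in 10 of 20 cases, also over the list alone (median -0.45, camera adjusted p = 1.94e-05), with Hemgn at -3.86, Car2 at -3.24, Gata1 at -2.98 and Samd14 at -2.46.

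Mast cell genes fell in 10 of 14 cases and rose in 1, also over the list alone (median -1.95, camera adjusted p = 1.2e-06), with Mcpt4 at -2.99 (to background), Cpa3 at -2.76, Gata2 at -2.72 and Mitf at 1.69. Stem cell genes fell in 17 of 22 cases and rose in 1, also over the list alone (median -0.91, camera adjusted p = 1.54e-09), with Tek at -3.48, Angpt1 at -1.81, Sox4 at -1.73 (-1.09 with probe sets averaged) and Egr1 at -1.33. Early T cell genes fell in 10 of 16 cases and rose in 3, also over the list alone (median -0.77, camera adjusted p = 0.00369), with Cd7 at -3.64 and Cd28 at 1.70, and 1 of the falls and 1 of the rises were at background in both groups. Here too only Cd28 was left among the brighter genes, which reversed the direction and ended the call (adjusted p = 0.164, the lowest over camera's alternatives being 0.00046). Ribosome biogenesis and MYC genes fell in 18 of 21 cases, also over the list alone (median -0.40, camera adjusted p = 5.68e-08), with Dkc1 at -0.84, Nop58 at -0.76, Odc1 at -0.74 and Gnl3 at -0.51.

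Macrophage genes rose in 19 of 21 cases and fell in 2, also over the list alone (camera adjusted p = 4.22e-11), with Adgre1 at 2.85, Cd68 at 2.41, Mrc1 at 2.38, Cd14 at 1.91, Mpeg1 at 1.87 and Cybb at 1.5. The 2 falls were those of the MHC class II genes H2-Aa (-0.53) and H2-Ab1 (-0.45). Interferon-response genes rose in 16 of 17 cases, also over the list alone (median 1.39, camera adjusted p = 1.31e-09), with Mx1 at 2.82, Oas1a at 1.74, Ifit3 at 1.71, Ifit1 at 1.62 and Rtp4 at 1.52. The p53 response list had 11 lower and 5 higher of 19, or 11 and 6 over the list alone, with Perp at -2.68, Eda2r at -1.61, Aen at -0.43 and Fas at 2.43 (median -0.29, camera adjusted p = 0.0419). That call was lost with an estimated correlation (adjusted p = 0.0869 with an estimated correlation), with quantile normalization (0.0814) in the brighter part of the genes (0.162) and among genes without equal values (0.122). It was lost as well without OP9-DL1 replicate 1 (0.0583), OP9-DL1 replicate 2 (0.061) or Compound E replicate 1 (0.0578). Immediate early genes had 12 lower, 1 of them at background in both groups, and 5 higher of 21, also over the list alone, with Egr2 at -1.84, Hspa1b at -1.43, Atf3 at 1.70 and Hmox1 at 1.24 (median -0.32, camera adjusted p = 0.0091), and adjusted p was 0.0542 with an estimated correlation and 0.0804 in the brighter part of the genes. Not called were the granulocyte list (8 higher and 6 lower of 19, camera adjusted p = 0.965, with Csf3r at 1.84 and Ltf at -1.40), the B cell list (4 and 4 of 18, 2 of the higher ones at background in both groups, adjusted p = 0.586, median 0.05, mean -0.12) and the cell cycle list (6 and 5 of 25, adjusted p = 0.57, median -0.06, mean 0.01). Their counts were the same over the list alone. Cholesterol synthesis genes had 8 higher and 1 lower of 17, also over the list alone, led by Mvd at 1.47 and Pmvk at 0.61, and missed the threshold (camera adjusted p = 0.0562). They passed the threshold when arrays were centred on their medians (0.0146) or quantile normalized (0.0497), without OP9-DL1 replicate 3 (0.0485) and without Compound E replicate 2 (0.0473). With log2(value + 32) the medians were -0.59 for Notch targets, -0.29 for early T cell, -1.18 for mast cell and -0.23 for erythroid genes. With probe sets averaged they were -0.37 for early T cell, -0.60 for stem cell and -0.18 for p53 genes, and with arrays centred on their medians -0.16 for p53 and -0.18 for immediate early genes. In the brighter part of the genes the erythroid median was -2.72 and the stem cell median -1.73. Among genes without equal values the medians were -1.01 for erythroid and -1.19 for mast cell genes. Each of these values was called.

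The third comparison set Compound E on OP9-DL1 against OP9-GFP, which asks how far the inhibited cultures differed from the control feeder. Differences were smaller: megakaryocyte, mast cell, stem cell and ribosome biogenesis genes lay below OP9-GFP, and interferon-response and cholesterol synthesis genes somewhat above. The megakaryocyte list was lower in 19 of 27 genes and higher in 1, with a median log2 change of -0.50. Of 13 Notch targets 2 were lower, Nrarp (-1.58, or -1.03 with probe sets averaged) and Myc (-0.81). Only 7 of the 13 were above background on OP9-GFP, and those at background there had little room to fall. Higher values were found for 2208 genes and lower ones for 1927, of which 110 and 137 differed at least 2-fold. The share of higher among changed genes was 53.4%, and 78.2% when each array was centred on its median and 43.4% over all probe sets. Groups did not overlap for 34.8% of genes, where chance gives 10%.

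Slc26a7 had the largest rise over OP9-GFP, from 3.50 ± 0.17 to 7.08 ± 0.12 (SD, n = 3), with a limma adjusted p of 3.72e-11. It was followed by Ptchd4 (2.94), Col8a1 (2.76), the granzyme gene Gzme (2.68) and Plxdc2 (2.67). Slc26a7 and Ptchd4 were at background on OP9-GFP, so the size and rank of their rises are uncertain. The largest change of another probe set was 0.00 for Ptchd4, 0.46 for Slc26a7 and 0.59 for Col8a1, and with probe sets averaged these genes stood at 1.47, 2.02 and 1.22, each still called. The complement genes C1qc (-2.63) and C1qb (-2.56), Ctnnd2 (-2.50), Fcer1a, the IgE receptor α chain of mast cells and basophils (-2.35), and Kctd14 (-2.21) were the 5 largest falls, with Ctnnd2 at -1.5 and Kctd14 at -1.34 when probe sets were averaged. C1qb was also lower on OP9-DL1 alone (-2.35), and Compound E against OP9-DL1 gave -0.21 (adjusted p = 0.107). Without Compound E replicate 1 that value was -0.31 with an adjusted p of 0.0272, and over all alternatives its adjusted p ran from 0.0272 to 0.481.

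Besides the megakaryocyte list (19 lower and 1 higher over the list alone, camera adjusted p = 1.63e-13), the mast cell list was lower in 8 of 14 genes and higher in 1, which was at background in both groups (8 and 2 over the list alone, median -0.59, adjusted p = 7.82e-08), with Cpa3 at -1.42 and Gata2 at -0.90. Rab27b stood at -0.80, Itgb3 at -0.68, Pf4 at -0.62 and Tubb1 at 0.62. The stem cell list was lower in 14 of 22, also over the list alone (median -0.40, adjusted p = 6.87e-12), with Tek at -1.34 and Angpt1 at -0.60. The ribosome biogenesis list was lower in 12 of 21 (16 over the list alone, median -0.29, adjusted p = 6.87e-12), with Dkc1 at -0.48 and Nop58 at -0.47. Erythroid genes were lower in 7 of 20, also over the list alone (median -0.13, adjusted p = 2e-04), with Hemgn at -1.74 and Car2 at -1.56. Cell cycle genes were lower in 12 of 25 (13 over the list alone, median -0.17, adjusted p = 2.16e-06), with Mcm6 at -0.32. Stromal markers moved both ways, 5 higher and 9 lower of 24 (7 and 9 over the list alone), with a median of -0.001 and adjusted p = 0.182. Col3a1 (1.20) and Fstl1 (0.57) were above OP9-GFP, and Timp3 (-0.75) and Ccn1 (-0.60, or -0.28 with probe sets averaged) below.

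Interferon-response genes were higher in 10 of 17 and lower in 1 (12 and 2 over the list alone, median 0.31, camera adjusted p = 0.00114), with Rtp4 at 0.84 and Ifit1 at 0.55. Cholesterol synthesis genes were higher in 8 of 17 (11 over the list alone, median 0.20, adjusted p = 0.000448), with Mvd at 0.87 and Pmvk at 0.52. Immediate early genes were higher in 11 of 21 and lower in 4 (14 and 4 over the list alone, median 0.18, adjusted p = 0.00386), with Hmox1 at 0.69 and Egr2 at -0.58. Granulocyte genes were higher in 10 of 19 and lower in 6 (12 and 6 over the list alone, median 0.22, adjusted p = 0.00416), with Ltf at 1.44, Camp at 1.22, Lcn2 at 1.17 and Csf3r at 1.10. The granulocyte call was lost with an estimated correlation (adjusted p = 0.101 with an estimated correlation). The erythroid median was -0.03 with log2(value + 32), -0.04 with arrays centred on their medians and -0.88 in the brighter part of the genes, where the mast cell median was -1.18. Centring gave -0.07 for cell cycle and 0.27 for immediate early genes. Among genes without equal values the mast cell median was -0.27 and the granulocyte median 0.35, and each of these values was called. Not called were Notch targets (0 higher and 2 lower, also over the list alone, called only in the brighter part of the genes at 0.0401, adjusted p = 0.28, median 0.04, mean -0.13) and the macrophage list (8 higher and 5 lower of 21, 8 and 6 over the list alone, adjusted p = 0.57). The early T cell list (1 and 2 of 16, 0 and 2 over the list alone, adjusted p = 0.586, median 0.02, mean -0.03), the B cell list (5 and 3 of 18, 2 and 1 of them at background in both groups, also over the list alone, adjusted p = 0.586) and the p53 list (4 and 5 of 19, 6 and 6 over the list alone, adjusted p = 0.586, median 0.11, mean -0.02) were not called either.

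The design also asks which genes stood apart on OP9-DL1 from both other groups. Of the 2888 genes higher on OP9-DL1 than on OP9-GFP, 2538 (87.9%) were also higher than with Compound E, and of the 3046 lower ones 2591 (85.1%) were also lower. Independent lists of these sizes would share 623.2 and 765.8 genes. Simulated unchanged groups that share the OP9-DL1 arrays gave 0 shared genes in 100 runs, but no run called more than 1 gene in a comparison, so this value could only be near 0 and does not measure what shared arrays add once genes change. By contrast 344 genes were higher, and 315 lower, than OP9-GFP in both OP9-DL1 groups, where independent lists would share 350.5 and 322.6. Each pair of comparisons shares 3 arrays, too few to split, so part of any excess may come from the shared arrays. A moderated F test over the 3 groups called 8543 of 18193 genes.

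Of the 748 genes at least 2-fold higher on OP9-DL1 than on OP9-GFP, Compound E lowered 731 (97.7%). After treatment 325 of the 748 did not pass the test against OP9-GFP, 148 were still above it, among them Slc26a7 and Chodl, and 275 were below it, among them Gzmb, Nrarp, Slc35d3 and Itgb3. Of the 502 genes at least 2-fold lower, Compound E raised 486 (96.8%). That left 194 that did not pass the test against OP9-GFP, 68 still below and 240 above. Both sets were chosen by their values on the same OP9-DL1 arrays that Compound E was compared with, which favours a reversal. Among all 18193 genes Compound E lowered 3926 and raised 4574. Across genes, which are not independent replicates, the change from OP9-GFP to OP9-DL1 and the change from Compound E to OP9-DL1 correlated with a Pearson r of 0.892 and a Spearman rho of 0.792. These changes share the OP9-DL1 arrays, and simulated unchanged groups gave an r of 0.501. No gene changes in the simulations, so that r reflects the shared arrays alone. It is no benchmark for data in which many genes change, and the same holds for the simulated r and shares of equal sign given next. The covariance of the changes was 0.317, against 0.00701 in simulated unchanged groups, and they had the same sign for 79.1% of genes, against 66.7%. For the changes from OP9-GFP to OP9-DL1 and from OP9-GFP to Compound E r was -0.137 and rho -0.161, and r was -0.235 with log2(value + 32) and -0.269 in the brighter part of the genes. In simulated unchanged groups this r was 0.5. The covariance was -0.0222 against a simulated 0.00699, and the sign was the same for 43.7% of genes, against a simulated 66.6%.

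**Figure D3:**
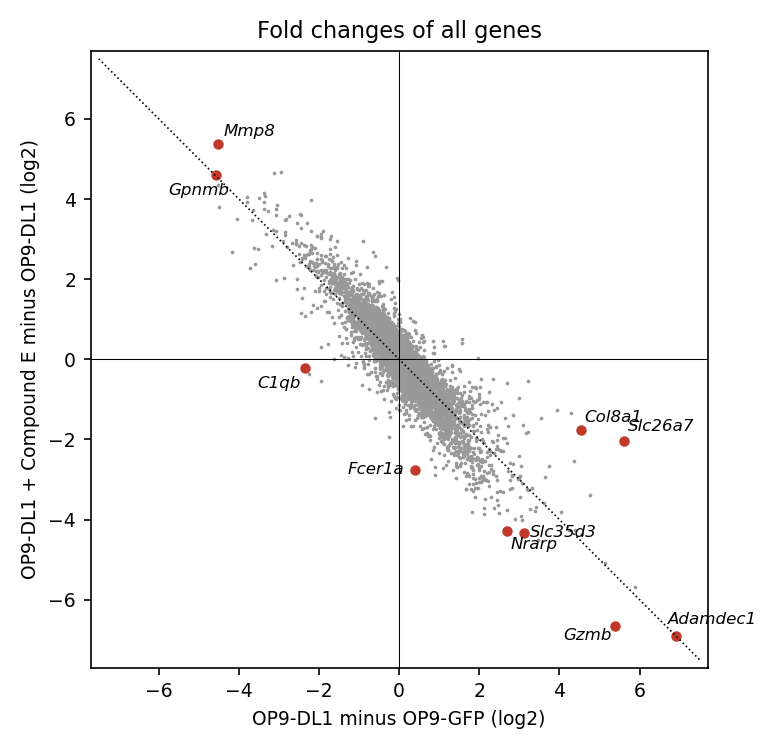
Log2 change with Compound E on OP9-DL1 (y) against log2 change from OP9-GFP to OP9-DL1 (x) for 18193 genes, 1 grey point each, with 10 named genes in red. The dotted line marks changes of equal size and opposite sign; Gpnmb (-4.56 and 4.60) lies by it, and C1qb (-2.35 and -0.21) lies near the horizontal axis.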

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

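Probe sets that carry no or several gene symbols were outside every comparison of genes, and they held signal above the control feeder. Of 10092 such probe sets, 807 were higher and 777 lower on OP9-DL1 than on OP9-GFP (limma adjusted p below 0.05, fitted over all probe sets). Among the higher ones 13 rose at least 8-fold. The one with the largest rise, which has no gene symbol, read 2.97 on OP9-GFP, 8.58 on OP9-DL1 and 3.07 with Compound E, and the next read 3.58, 9.06 and 3.63 (log2, means of 3 arrays). The one with the largest fall went from 8.20 to 4.59 and stood at 9.34 with Compound E. With Compound E 1114 were higher and 1982 lower than on OP9-DL1 alone. Groups of 3 arrays are too small for a check of single arrays that stand apart.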

How the results depend on the processing

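The filters on genes above background and on genes without equal values were chosen after seeing the data; the other alternatives were planned. For OP9-DL1 against OP9-GFP, Compound E against OP9-DL1 and Compound E against OP9-GFP, requiring a 2-fold change reduced the 5934, 8500 and 4135 changed genes to 1250, 1714 and 247, by construction, and testing all probe sets gave 11192, 17597 and 8552, since many genes have several. All other counts stayed within 1.5 times. Leaving out 1 array gave 5074 to 6268, 7372 to 8460 and 3059 to 4415 genes, 7470 to 8609 by the F test, 4479 to 5228 apart on OP9-DL1 from both other groups, and 33 to 35 called list tests. Genes above background gave 6125, 8153 and 4263. The 14217 genes with no equal values within a group gave 5339, 7415 and 3577, 7573 by the F test, 4598 apart on OP9-DL1, and 33 list tests, with 36.9%, 51.8% and 24.7% of them called in the 3 comparisons over all genes, against 17.4%, 28.4% and 15.5% of the 3976 others. Centring arrays on their medians moved the median gene by 0.13 in Compound E against OP9-DL1, from 0.08 to 0.21. It moved the share of higher genes from 53.8% to 73.7% there, from 53.4% to 78.2% against OP9-GFP, and from 49.5% to 38.9% among genes apart on OP9-DL1, so those splits depend on scaling. Over all probe sets the shares for Compound E were 48.9% against OP9-DL1 and 43.4% against OP9-GFP. The correlation of the changes from OP9-GFP and from Compound E to OP9-DL1 was 0.892, and 0.912 with log2(value + 32) and 0.913 in the brighter part of the genes. That of the changes from OP9-GFP was -0.137, and -0.235, -0.269 and, with probe sets averaged, -0.164; the cause was not tested. Among the brighter genes the early T cell list reversed to -2.11 and 1.70 in the first 2 comparisons, with 1 of 16 members left, and lost its call (adjusted p = 0.0804 and 0.164; ranges from 0.000216 and 0.00046). Of the 48 list tests 7 lost their call under at least 1 alternative, the early T cell ones included, 2 gained one with camera (cholesterol synthesis and, against OP9-GFP, Notch targets), and 5 others passed only with fry, which asks another question. Of the 375 values of the 125 named genes 20 lost and 16 gained a call under at least 1 alternative, and none reversed. With log2(value + 32) 21 of 116, 22 of 119 and 14 of 90 called values of these genes shrank by over 1.5 times, and with probe sets averaged 15, 17 and 9 did. Over camera's alternatives, fry left out, the adjusted p of the lists that lost a call with an estimated correlation ran from 0.0113 to 0.234 for cell cycle and 0.00371 to 0.17 for ribosome biogenesis on OP9-DL1, 0.0306 to 0.162 for p53 and 0.00189 to 0.0804 for immediate early genes with Compound E against OP9-DL1, and 0.00139 to 0.101 for granulocyte genes against OP9-GFP, and that of cholesterol synthesis from 0.0146 to 0.355. Replicate numbers did not pair the arrays: same-numbered arrays' deviations correlated from -0.115 to 0.119, over 0.1 in 2 of 9 pairs, and 4 of 9 arrays correlated best with their own number. With a replicate block 5755, 8295 and 3972 genes were called, 8314 by the F test, 4976 apart on OP9-DL1, and 34 list tests. Genes at background limit every fold they enter.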

Other observations

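Groups described here were chosen after their values were seen. Of 10 measured Schlafen genes, a family induced by interferon, 8 were lower on OP9-DL1 than on OP9-GFP and 8 were higher with Compound E than without, with medians of -1.35 and 1.79, or -0.58 and 1.01 with log2(value + 32). Slfn5 fell by 2.86 to background on OP9-DL1 and rose by 3.47 with Compound E, and Slfn2, the brightest at 11.85 on OP9-GFP, changed by -1.57 and 2.02. Of 10 granzyme genes 4 rose on OP9-DL1: Gzmb, Gzme (3.94), Gzma (3.31) and Gzmc (2.23), the last 2 from background. Gzme stayed 2.68 above OP9-GFP with Compound E, while Gzma returned to background (3.13). GATA factors rose in 4 of 6 cases, Gata1, Gata2, Gata3 and Gata6 (0.66), the last 2 from background. Of 8 GIMAP genes, which encode GTPases of lymphocytes, 4 rose, among them Gimap9 (2.43), Gimap6 (1.80) and Gimap1 (1.64), and these 3 fell below OP9-GFP with Compound E, at -1.07, -1.45 and -0.63. Of 9 Notch receptor and ligand genes 2 rose and 2 fell on OP9-DL1 (median -0.03), or 2 and 0 with probe sets averaged. Among them the Notch ligand gene Jag1 rose by 1.96 on OP9-DL1 and fell by 1.48 with Compound E. Under 4 alternatives (log2(value + 32), quantile normalization, centring on array medians and averaged probe sets) 8 Schlafen genes were lower each time. In them 4 or 5 granzyme genes and 3 or 4 GIMAP and GATA genes rose. The genes named here kept their directions and calls on OP9-DL1, with 1 exception given below. With log2(value + 32) rises were smaller, by over 1.5 times for Gzma (1.5), Gzmc (0.84), Gzme (2.38), Gimap1 (0.91), Gata3 (0.61) and Gata6 (0.21), and Slfn5 stood at -1.18 on OP9-DL1 and 1.61 with Compound E. On that scale the values with Compound E against OP9-GFP were 1.37 for Gzme, -0.69 for Gimap9, -0.70 for Gimap6 and -0.22 for Gimap1. With probe sets averaged Jag1 stood at 1.25 and -0.84, and Gimap6 at -0.74 against OP9-GFP. The exception among the calls was Gata6, which was not called when probe sets were averaged (0.18, adjusted p = 0.236). Centring arrays on their medians added 1 GATA gene lower on OP9-DL1.

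C1qb and C1qc, which encode complement chains made by macrophages, were lower in both OP9-DL1 groups than on OP9-GFP, C1qb at -2.35 without and -2.56 with Compound E, and C1qc at -2.26 and -2.63, or -1.38 and -1.52 with log2(value + 32). The remaining measured chain of 3, C1qa, was at background in every group and was not called (-0.18 and -0.17, adjusted p = 0.284 and 0.321), and 19 of 21 macrophage genes rose with the inhibitor. Il7r, the interleukin 7 receptor gene, was lower in both too, at -1.14 and -1.06, and Dntt, a DNA polymerase of lymphoid progenitors, was higher in both, at 2.02 and 1.34. Under the same 4 alternatives C1qb, C1qc, Il7r and Dntt were called in both comparisons each time.

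The tests of the 3 patterns that follow were chosen only after the results were seen. Stromal markers were higher on OP9-DL1 than on OP9-GFP, 17 of 24 with a median of 0.59. A fixed difference between the 2 feeder lines would not by itself lower the list with Compound E on the same line, where the median was -0.565. Without a group on OP9-GFP with Compound E, a separate effect of the drug on these genes cannot be told apart. A fixed difference as the cause of the rise therefore stays open. More feeder RNA carried over on OP9-DL1 should raise bright stromal transcripts alike. Of 10 members with a mean above 10, however, 5 had a 95% interval below the list's median and 2 above it. They ran from Fn1 (-0.13, interval -0.25 to -0.01) to Fstl1 (1.33). Acta2 is 1 of the 2 above, and with its probe sets averaged it stood at 0.085 (limma adjusted p = 0.552). On the same line, where the feeder lines do not differ, less feeder RNA carried over with Compound E should lower them alike, but Fn1 rose by 0.42 and the others ranged from Igfbp4 (-0.27) and Serpinf1 (-0.38) to Fstl1 (-0.76) and Acta2 (-1.14), with 3 above the list's median and 3 below it, or 2 below without Acta2, whose calls ended when its probe sets were averaged. These values are unequal, so carry-over alone is doubtful, but with so few members on each side it stays open, as do changes of single genes in the feeder cells and expression in the harvested blood cells.

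Megakaryocyte genes were lower with Compound E than on OP9-GFP, with a median of -0.50. Quantile normalization gave a median of -0.486 and centring arrays on their medians -0.408, and both were called. With log2(value + 32) and with probe sets averaged, which do not rescale arrays against each other, it was -0.408 and -0.482, also called. These alternatives start from the deposited values and moved the median gene by at most 0.09 in this comparison. So the direction does not depend on them, but they cannot test the scaling behind the deposited values. One candidate explanation is low Notch signalling on OP9-GFP that the inhibitor removed. Of 7 Notch targets above background on OP9-GFP, 2 were lower with Compound E, Nrarp and Myc, which leaves it open. Without a group on OP9-GFP with Compound E, an effect of the drug outside Notch or of the OP9-DL1 line cannot be told apart from it.

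Granulocyte genes moved both ways on OP9-DL1, 7 higher and 9 lower of 19. A changed share of granulocytes alone would move them together, unlike the 7 rises beside 9 falls. These counts are the pattern itself, so they do not test that explanation separately. A faulty Mmp8 probe set could account only for the fall of Mmp8, as 8 other members fell. That count followed from the 9 falls already seen, so it is no separate test. Mmp8 has no second probe set to check its own value. A difference in maturity of the granulocytic cells remains open, as a hypothesis that was not tested.

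Other splits of the arrays were counted as planned. For each pair of groups the 6 arrays allow only 10 splits, too few for a share under 0.05. The real splits called 5934, 8500 and 4135 genes, and the highest of the other splits called 0 in each. From the 280 splits of the 9 arrays into 3 groups 100 were counted, the real one by design and the others drawn at random. The share as large as the real one could thus not be below 1 of 100. Only the real one reached 8543 genes by the F test, and the highest other gave 5258. That split kept the OP9-DL1 arrays together, and the highest that did not gave 454, so a random grouping of these arrays can be excluded. Replicates may be technical, and then the splits cannot exclude chance differences between cultures. With the same limit, a random grouping can be excluded for the 5129 genes apart on OP9-DL1 from both other groups. For these 840 splits are possible because any group can be the one held apart. Of 100 counted, again with the real one included by design, only the real one was as large, and the highest other gave 378. The draw of the others held none of the 11 splits that follow the real groups most closely. Run one by one after the draw was seen, these gave 659 with OP9-GFP held apart, 3251 with the Compound E arrays held apart, and 4188 to 4307 in the 9 that hold OP9-DL1 apart and mix the other 6 arrays, all below the real count. For the 34 called list tests only the real one of the 100 splits, included by design, was as large. The highest other gave 33 and the median 24, so the count of camera calls hardly separates the real groups from other splits.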
